A study of Mus musculus with 12 samples.

How the data were processed

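The series holds polyadenylated, strand-specific RNA sequencing of mouse embryonic stem cells (ESCs), 12 libraries in 4 groups of 3: Dicer1 knockout, the wild-type line TFC set against it, Dgcr8 knockout, and the wild-type line V6.5 set against that. Per the labels' protocols, cells grew on gelatin in serum medium with leukaemia inhibitory factor (LIF), RNA was taken with Trizol, and strand was kept by the UTP method. Per the submitters' processing notes, TopHat2 2.0.12, DESeq and the mouse build mm10 were used. How reads were assigned to exons and introns, and by which annotation, is not given in the sources used here.

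The authors deposited 4 tables of normalised reads, a signal scaled by a size factor per library: exonic and intronic reads of the Dicer pair, and of the Dgcr8 pair, for 18412 genes. Each column is a group mean, per the file headers 1 column per genotype, so levels are given as the authors' group means with no SD or n. Each table was scaled on its own, so tests were made within a table, and levels are not compared between tables. Reads of near-identical gene copies and of overlapping genes may be split or shared by the authors' counting. Values of such genes are uncertain, among them Slfn3 and Slfn9, Rhox5 and Rhox6, and Ddx3y.

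The tests had been planned for values per library, which the tables do not list. Each deposited group mean is printed in full and is a whole-number combination of 3 steps, 1 step per library. Solving for these steps gave the size factors, 0.394 to 2.40 in exons and 0.338 to 1.97 in introns, and each gene's whole reads in each library. Between 99.45% and 100.0% of the genes of a column had 1 solution. In exons, genes of high level had several, 62 and 102 for Dicer knockout and wild type, 94 and 7 for Dgcr8. Of these, 20 and 24, and 15 and 1, were kept because only 1 solution put the 3 libraries close together. This rule favours a small spread in those genes. The other 42 and 78, and 79 and 6, were left out, and in introns at most 1 per column was. In simulated columns, 99.34% and 99.69% of 18412 genes had 1 solution, and 100.0% of these were right. Size factors recomputed by the median-of-ratios method from the recovered reads differed from the solved ones by -0.515 to 0.358% in exons. Of the recovered read numbers, 60.2 to 78.0% in exons and 60.9 to 80.4% in introns were even, where independent single reads would give as many even as odd numbers. Precision is therefore lower than the read totals imply, and no counting interval is given.

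Recovered libraries carry no replicate number of the labels, and are called A, B and C. A is the library of each group with the lowest mean correlation with the other 2 in the exon table, and B and C follow by size factor. Intronic libraries took the letter of the exonic library whose deviations they followed best. For A this was clear (r of 0.4 to 0.57 across genes), for B and C weak (r of 0.029 to 0.17). No 2 libraries of a group agreed within sampling noise: the lowest chi-square per gene was 22.1 in exons and 14.3 in introns. Exonic depth was 5914267 to 32768533 recovered reads per library, and intronic depth 559057 to 5597604.

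Tests were made with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a trend on level) on log2(value + 1), knockout minus wild type. Genes with a mean of at least 10 over the 6 libraries of a table were tested. A fold change is a difference of group means on the log2(value + 1) scale. The added 1 understates the change of low genes, while a library at or near 0 can widen it beyond the ratio of the group means, as for Smyd1 in Dicer exons (log2 fold change 8.003, ratio of means 125.6). Benjamini-Hochberg adjusted p under 0.05 counts as called, with 4 residual degrees of freedom. Exonic against intronic change was tested on log2 exonic minus log2 intronic values, centred on each library's median. Effects in Dicer and Dgcr8 were compared by a contrast of both over 12 libraries. An exact permutation test of 3 against 3 libraries can reach no two-sided p under 0.1. Nothing in the labels says that libraries of a group came from separate cultures. The p-values of single genes thus measure only the spread between these libraries, which may be technical.

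Altogether 26 lists of pathway genes and cell-type markers were set. Those of microRNA host genes and X dosage had 0 genes in the deposited data and were not tested, nor were lists with too few measured genes. Camera was run at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. At the preset correlation its p-values rest on the number of genes. With an estimated one, its degrees of freedom are limited to those of the libraries, 4 here. These p-values thus differ by more than the correlation. Genes with a 7-base match to each of 10 microRNA seeds (6 of ESC families, 4 for comparison) in the longest annotated 3' UTR were tested by camera. Their median was also set against 10000 random lists matched in 10 bins of level and 10 of 3' UTR length. The GENCODE M21 annotation (GRCm38, the assembly of mm10) held 97.9% of the gene symbols, and 96.9% had a 3' UTR. Coordinates are 1-based from this annotation.

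Tests, lists, seeds and the naming rule were chosen before the data were examined. The rule names the targeted genes; per exon comparison the 10 highest and 10 lowest fold changes among called genes with a group mean of at least 50, groups that do not overlap and a proper symbol; up to 4 called members of each list; 11 fixed genes of pluripotency, Tgf-β signalling and known microRNA targets; up to 6 genes up and 6 down in both comparisons and 4 per opposite direction; and 4 high and 4 low intronic genes per comparison. Of the genes this rule names, 1 is not reported here.

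In simulated Dicer exons of 13546 genes, limma called 0% of genes changed 2-fold, 29% of those changed 4-fold, and 0 unchanged genes. In simulated Dgcr8 exons (13056 genes) it called 0% of either size. With the library-set term, chosen after seeing the data, it called 99% and 100% of 2-fold changes in these, with 6 and 3 unchanged genes, and 99% and 100% of 4-fold changes in exon minus intron, with 8 and 5. The simulated reads hold the deviation of library A by construction, so part of this gain is built in. Within a simulated comparison, all genes and libraries shared 1 dispersion, the median from knockout B and C, so noisier real libraries may give fewer calls. Camera found 1 of 1 raised lists and 0 of 20 unchanged ones in the Dicer simulation. Its genes were drawn independently and its unchanged lists at random, so this could not test the preset correlation for lists of correlated genes.

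Alternatives planned beforehand were other pseudocounts (0.5 and 8), filters, scalings, variance models, fold minima and seed definitions, and leaving out each library. After seeing the data, these were added: a term for library set (A against B and C of each group), B and C alone, limma-voom on recovered reads, other pairings of exonic and intronic libraries, an estimated correlation for seeds, and lists and seeds without each library. Planned count-model tests, and fits with the labels' replicate number, were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.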

Results

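PolyA RNA was sequenced from 3 libraries each of ESCs lacking Dicer1, the nuclease that cuts hairpin precursors into microRNAs, and of ESCs lacking Dgcr8, the RNA-binding partner of Drosha in the nuclear step of microRNA production. Each was set against 3 libraries of its own wild-type line, TFC for Dicer and V6.5 for Dgcr8. The comparisons ask how exonic and intronic RNA differs in lines with a stable loss of either factor. The title of the study concerns loss of Argonaute and the Tgf-β/Smad network. Each comparison sets a knockout line against a wild-type line, and the libraries replicate lines. The loss of a factor thus cannot be told apart from other differences between the lines. Libraries A, B and C held 29366570, 17885555 and 14944705 exonic reads in the Dicer knockout, 32768533, 16762578 and 13539908 in TFC, 31329487, 18773531 and 18692241 in the Dgcr8 knockout, and 5914267, 16811016 and 10370282 in V6.5. In every group, A correlated with B and C at r of 0.709 to 0.854 over exonic genes, and B with C at 0.835 to 0.969. A is the library with the lowest mean correlation by definition.

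Dicer1 (chromosome 12, 104687742 to 104751952, minus strand) had 1333.5, 1762.9 and 1674.5 normalised exonic reads in knockout libraries A, B and C, and 2943.8, 3277.8 and 3496.4 in TFC. The log2 fold change was -1.03 (SE 0.23), and the groups did not overlap, but limma's adjusted p was 0.0736 (0.00198 to 0.37 over the alternatives, lowest with a term for library set). Dgcr8 (chromosome 16, 18253948 to 18289246, minus strand) had 342.1, 955.5 and 1113.6 reads in its knockout and 1929.8, 2707.1 and 2947.1 in V6.5. Its log2 fold change was -1.80 (SE 0.47), again with groups that did not overlap, and an adjusted p of 0.111 (0.00131 to 0.397 over the alternatives). These levels cover all exons, and the deleted part is not named in the labels, so they are no check of a null allele. Each untargeted factor did not pass: Dgcr8 stood at 4640 and 3803 reads in Dicer knockout and TFC (adjusted p = 0.689), and Dicer1 at 5430 and 4511 in Dgcr8 knockout and V6.5 (adjusted p = 0.735).

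**Figure D1:**
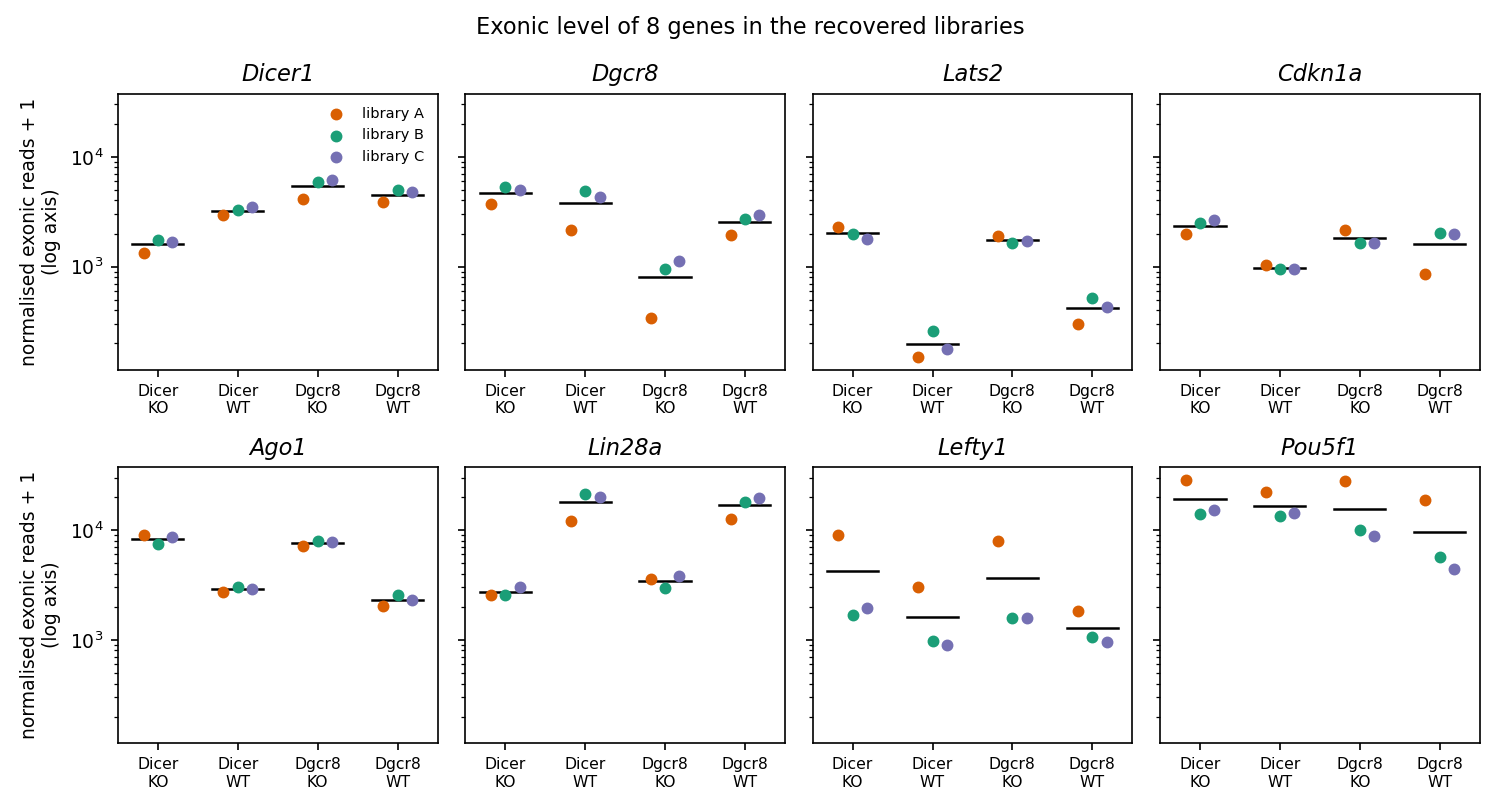
Normalised exonic reads + 1 (log axis) of 8 genes in each recovered library, letters A, B and C, of the 4 groups; horizontal bars are group means. Lats2 and Ago1 lie higher and Lin28a lower in both knockouts than in their wild-type lines, while Pou5f1 did not pass the test in either comparison.

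In Dicer knockout exons, Lats2, the Hippo pathway kinase and a known target of the miR-290 and miR-302 families, rose 10.3-fold from a mean of 195.9 normalised reads in TFC to 2018 (log2 fold change 3.39, SE 0.35; adjusted p = 0.00807). Casp2, an apoptotic caspase, rose to 1746 from 470.7 reads, and Cdkn1a, the cell-cycle inhibitor p21, to 2361 from 976.9. Ago1, an Argonaute, rose to 8338 from 2874 reads, and Tnrc6a and Tnrc6b, Argonaute-binding proteins of the silencing complex, to 9573 from 3710 and to 5841 from 2561. Lin28a, the RNA-binding protein that blocks let-7 maturation, fell by 2.68 on the log2 scale (SE 0.27; 2710 against 17874 reads; adjusted p = 0.00807). Dnmt3l, a cofactor of de novo DNA methylation, fell by 2.54 (SE 0.24; 1356 against 8052 reads; adjusted p = 0.00807).

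Among the highest fold changes in Dicer knockout, Smyd1, a muscle methyltransferase, rose from 18.59 to 2336 reads (125.6-fold), Msln, mesothelin, from 62.38 to 2023 (log2 fold change 5.04, SE 0.45) and the imprinted zinc-finger gene Plagl1 from 185.2 to 4413 (4.68, SE 0.42). Loxl4, a lysyl oxidase, rose from 9.63 to 924.5 reads, Fat2, a protocadherin, from 17.9 to 1072 and Sh3rf2 from 4.64 to 516.6. Wild-type levels were lower still for C1qtnf9 (402.9 against 2.14 reads; log2 fold change 7.49) and Nmi (220.8 against 0.417; 7.27), and Pou3f2, a neural POU factor, stood at 207.7 reads and was listed at 0 in TFC. Among the lowest, Usp26 stood at 1.70 against 645.0 reads (log2 fold change -8.36) and Slfn3 at 0.757 against 217.2 (-7.19). Zmat4 fell by 4.56 (SE 0.57), from 2647 to 114.2 reads. Pim2, a survival kinase, fell by 3.08 (SE 0.35), and Eps8 (-3.73), Slfn9 (-3.33), Prune2 (-2.97), Tro (-2.85) and Lpl, lipoprotein lipase (-2.80), fell too. These genes had adjusted p of 0.00807 to 0.0487.

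Of 13196 genes tested in Dicer exons, limma called 132 higher and 30 lower in the knockout, 162 in all. At an unadjusted p under 0.05 there were 1911, and in 2825 genes (21.4%) the groups did not overlap. A share of 10% would arise if every library could equally stand in either group. Library A deviated from B and C in every group, so 10% is not the share due to chance here. With the library-set term, chosen after seeing the data, 957 rose and 663 fell, all 162 among them, while 35 were called without a variance trend and 21 with limma-voom. Calls numbered 86 without knockout library A, 0 without B, 0 without C, 480 without wild-type library A, 7 without B and 0 without C. In the 3 cases of 0, there were 1207, 1155 and 1519 genes at an unadjusted p under 0.05.

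Genes known as miR-290 targets rose together in Dicer knockout exons. All 14 measured members were higher in the knockout (median log2 fold change 1.27; camera adjusted p = 2.32e-09, and adjusted p = 0.107 with an estimated correlation). Of these, 3 were called up (Lats2, Casp2 and Cdkn1a) and 0 down, adjusted over the list alone 9 up and 0 down, and with the library-set term 9 and 0. The G1/S cell-cycle list, which shares Lats2 and Cdkn1a with it, also rose: 19 of 23 members were higher, 2 called up and 0 down, adjusted over the list alone 6 and 0, with the library-set term 8 and 0 (median 0.71; camera adjusted p = 0.000157, adjusted p = 0.107 with an estimated correlation). Rbl2, a pocket protein in both lists, stood at 875.7 against 316.3 reads and did not pass (adjusted p = 0.11; 0.0148 with the library-set term, in a range of 0.0148 to 0.487 over the alternatives). Both lists passed without any 1 library.

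Smad2/3 target genes were higher as a list in Dicer knockout, in 17 of 20 members (median log2 fold change 0.51; camera adjusted p = 0.00527, adjusted p = 0.199 with an estimated correlation). Of these, 1 was called up, Ctgf, a matricellular growth factor that rose to 3127 from 962.5 reads (1.72, SE 0.25; adjusted p = 0.0278), and 0 down; adjusted over the list alone the count was again 1 and 0, and with the library-set term 3 and 0. Of 20 measured components of Tgf-β signalling, 0 were called by limma, and adjusted over the list alone 0 (13 higher, 7 lower; camera adjusted p = 0.382). With the library-set term 2 were called up. Lefty1 and Lefty2 belong to both the Smad2/3 and the miR-290 target lists. Lefty1 stood at 4215 against 1629 reads (log2 fold change 1.16, SE 0.68; adjusted p = 0.49, and 0.00292 to 0.804 over the alternatives). Library A was high in both groups: libraries A, B and C held 9028.7, 1673.2 and 1942.8 reads in the knockout and 3013.4, 980.5 and 894.6 in TFC. The log2 fold change was 1.58 within A and 0.94 within B and C. With the library-set term Lefty1 was called (adjusted p = 0.00292), and leaving out the A library of 1 group gave 0.38 (knockout) or 1.72 (TFC). Among other pathway genes named in advance, Lefty2 stood at 5669 against 4191 (0.433), Tgfbr2 at 198.2 against 71.44 (0.452), Smad7 at 1343 against 902.4 (0.659) and Skil at 6920 against 6032 (0.75), adjusted p in brackets. Of 22 BMP pathway genes, 0 were called up or down, and adjusted over the list alone 2 up and 1 down (camera adjusted p = 0.276).

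Trophectoderm markers were higher in Dicer knockout in 9 of 10 members (median 2.56; camera adjusted p = 0.00171, adjusted p = 0.407 with an estimated correlation), although 0 were called singly by limma, 2 up and 0 down adjusted over the list alone, and 2 up with the library-set term. The p53 and apoptosis list was higher in 15 of 21 members (median 0.43; camera adjusted p = 0.0211, adjusted p = 0.199 with an estimated correlation), with Casp2 and Cdkn1a called up and 0 down, 5 and 0 adjusted over the list alone. This list shares Casp2, Cdkn1a and Ei24 with the miR-290 target list, and without wild-type library C its camera adjusted p was 0.122. Ribosomal protein genes were lower in 24 of 25 members by a small amount (median -0.42; camera adjusted p = 0.000157, adjusted p = 0.132 with an estimated correlation), with 0 called by limma, 0 adjusted over the list alone, and 8 down with the library-set term. Fibroblast markers, a sign of feeder cells, did not pass (13 tested, 0 called, median -1.23; camera adjusted p = 0.382).

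Pluripotency genes went both ways in Dicer knockout. Of 25 naive pluripotency genes, 0 were called up and 2 down, Lin28a and the nuclear receptor Nr5a2, which fell by 1.53 (1159 against 3410 reads), and adjusted over the list alone 2 up and 4 down (median 0.03, mean -0.14, camera direction down; adjusted p = 0.571). Pou5f1 (19210 against 16642 reads; adjusted p = 0.871), Nanog (18692 against 14970; 0.591) and Sox2 (21414 against 23129; 0.888) did not pass. Imprinted genes held 3 called up, Plagl1, Igf2 (2152 against 348.6 reads) and Peg3 (17935 against 7018), and 1 down, Grb10 (3481 against 8359), and adjusted over the list alone 4 and 3 (15 tested; camera adjusted p = 0.0994). Primitive endoderm markers held 2 called up, Sparc, a matrix protein, at 20894 against 4281 reads and Col4a2 at 697.7 against 131.1, and adjusted over the list alone 4 up and 1 down (14 tested; median -0.13, with a camera direction of up; adjusted p = 0.382). Single members called in lists that did not pass were Rhox6 (germline, 850.8 against 175.7 reads), Gadd45a (stress response, 2077 against 742.8; list median -0.35, mean 0.41, camera direction down) and Dnmt3l (DNA methylation; list median 0.14, mean 0.03, camera direction down). Of 13 microRNA pathway genes 3 were called up, Ago1, Tnrc6a and Tnrc6b, and 0 down, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0796).

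In Dgcr8 knockout exons, Rbl2 rose to 731.9 from 102.4 reads in V6.5 (log2 fold change 2.83, SE 0.42; adjusted p = 0.0315), Lats2 to 1747 from 416.5 (2.10, SE 0.31; 0.0312), Ei24, an endoplasmic reticulum protein induced by p53, to 5458 from 1576 (1.79, SE 0.23; 0.0245) and Ago1 to 7586 from 2286 (1.74, SE 0.23; 0.0266). Otx2, a homeobox factor of the epiblast and forebrain, rose to 1914 from 250.6 reads, and Zeb1, a repressor of epithelial genes, to 1022 from 143.8. Lower in the knockout were markers of mesoderm, trophectoderm and fibroblasts. T (brachyury), a primitive streak factor, was listed at 0 against 1443 reads, Krt8 and Krt18, keratins of simple epithelia, fell (log2 fold changes -4.42, SE 0.68; 314.0 against 5087 reads, and -5.55, SE 0.76; 171.4 against 5209), as did Col1a1, a fibrillar collagen (-5.12, SE 0.64; 47.98 against 1374 reads). Lin28a fell by 2.27 (SE 0.28), from 16812 to 3457 reads (adjusted p = 0.0244).

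Among the highest fold changes in Dgcr8 knockout, Msln rose from 33.92 to 1752 reads (log2 fold change 5.66, SE 0.48; adjusted p = 0.0127), Hhip, a hedgehog-binding protein, from 31.9 to 1077, Fat2 from 23.81 to 743.6, Smyd1 from 59.44 to 1805 (4.98, SE 0.46), Sohlh2, a germ-cell factor, from 27.42 to 644.4 and Rapgef4 from 8.15 to 246.6. Megf11 stood at 727.9 against 7.14 reads, Skida1 at 635.5 against 3.19 and Pkhd1 at 209.5 against 1.69 (log2 fold changes 7.23, 8.15 and 6.85), and Napsa at 106.6, listed at 0 in V6.5. Among the lowest, Slc6a14 (352.3 reads in V6.5), Tmem200a (339.6), Bmp2 (220.9), Plac8 (213.6) and Zfhx4 (158.7) were listed at 0 in the knockout. The Y-linked genes Eif2s3y and Uty stood at 3.11 and 3.11 against 1213 and 401.2 reads, Usp26 at 3.11 against 432.3 and Tmprss2 at 0.518 against 244.8 (log2 fold changes of the last 3 -7.49, -7.34 and -7.24). Igf2, an imprinted growth factor, fell by 3.72 (SE 0.30), from 7871 to 615.6 reads (adjusted p = 0.0127). Cldn6, a tight-junction protein, fell by 4.52, and Dab2, an endocytic adaptor (-4.86), and Rhox5 (-4.38) fell too.

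Of 12758 genes tested in Dgcr8 exons, limma called 95 higher and 66 lower, 161 in all. At an unadjusted p under 0.05 there were 2072, and in 2869 genes (22.5%) the groups did not overlap. With the library-set term 1062 rose and 1098 fell, all 161 among them, with libraries B and C alone 2028 were called, and with limma-voom 50. Calls numbered 466 without knockout library A, 0 without B, 0 without C, 382 without wild-type library A, 0 without B and 0 without C. In the 4 cases of 0, there were 1329, 1440, 1270 and 1500 genes at an unadjusted p under 0.05.

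The miR-290 target list rose in Dgcr8 knockout as well: 12 of 15 members were higher, 3 called up (Lats2, Rbl2 and Ei24) and 0 down, adjusted over the list alone 6 up and 1 down, and with the library-set term 9 and 1 (median 1.05; camera adjusted p = 6.95e-05, adjusted p = 0.233 with an estimated correlation). G1/S cell-cycle genes were higher in 19 of 23 members, with Ccnd2, a D-type cyclin (2550 against 645.1 reads), Lats2 and Rbl2 called up and 0 down, 6 and 0 adjusted over the list alone, and 10 and 0 with the library-set term (median 0.69; camera adjusted p = 0.000237, adjusted p = 0.233 with an estimated correlation). Cdkn1a stood at 1810 against 1621 reads and did not pass (adjusted p = 0.833). Naive pluripotency genes were higher in 20 of 25 members (median 0.83; camera adjusted p = 0.0012, adjusted p = 0.573 with an estimated correlation), but 1 was called up, Prdm14, a germline and naive-state regulator (695.0 against 122.3 reads), and 1 down, Lin28a, 2 and 2 adjusted over the list alone, and 11 and 2 with the library-set term. Pou5f1 stood at 15642 against 9585 reads (adjusted p = 0.617), Nanog at 12344 against 7144 (0.24) and Sox2 at 16618 against 7854 (0.27), not past the test. In V6.5 libraries A, B and C, Sox2 stood at 14127.8, 2614.6 and 6818.7 reads and Nanog at 9930.6, 4604.1 and 6896.8. Within A the log2 fold changes were 0.39 and 0.34, and within B and C 1.89 and 1.12. With the library-set term adjusted p of Pou5f1, Nanog and Sox2 were 0.0145, 0.0268 and 0.0305. Over the alternatives they ranged from 0.0145 to 0.906, 0.0268 to 0.625 and 0.0305 to 0.624.

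Lists of mesoderm, trophectoderm, fibroblast, BMP pathway, imprinted and Y-linked genes were lower in Dgcr8 knockout than in V6.5. Mesoderm and streak markers were lower in 9 of 11 members, 2 called (T and Wnt3, a streak ligand, 12.44 against 652.1 reads) and 0 up, 4 adjusted over the list alone (median -1.55; camera adjusted p = 0.00162, adjusted p = 0.296 with an estimated correlation). Trophectoderm markers were lower in 10 of 13, with Krt8 and Krt18 called and 0 up, adjusted over the list alone 6 down and 1 up (median -1.55; camera adjusted p = 0.000461, adjusted p = 0.352 with an estimated correlation). Fibroblast markers, which feeder cells would carry, were lower in 12 of 15, with Col1a1, Acta2 and Tagln called and 0 up, adjusted over the list alone 7 down and 1 up (median -2.45; camera adjusted p = 0.000461, adjusted p = 0.387 with an estimated correlation). BMP pathway genes were lower in 19 of 24, with the ligands Bmp2, Bmp4 (28.62 against 578.3 reads) and Bmp8b (66.35 against 426.3) called and 0 up, 4 adjusted over the list alone (median -0.67; camera adjusted p = 0.015, adjusted p = 0.352 with an estimated correlation). Imprinted genes were lower in 12 of 14, with Igf2 called and 0 up, 3 adjusted over the list alone (median -0.74; camera adjusted p = 0.00414, adjusted p = 0.296 with an estimated correlation). Y-linked genes were lower in 3 of 3, with Eif2s3y and Uty called and 0 up, 3 adjusted over the list alone (median -7.49; camera adjusted p = 0.000168, adjusted p = 0.296 with an estimated correlation). These 6 lists passed without any 1 library, but they are not independent, as the mesoderm and trophectoderm lists share Eomes and Hand1. The streak genes differed among the V6.5 libraries A, B and C, with 66.02, 2021.3 and 2242.6 reads of T and 157.4, 912.7 and 886.2 of Wnt3. Without V6.5 library B or C neither was called (limma adjusted p = 0.226 and 0.179 for T, 0.263 and 0.21 for Wnt3). In these fits no exonic gene was called, so the loss is not particular to T and Wnt3.

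Neuroectoderm markers were higher in 7 of 11 members, with Ncam1, a neural adhesion molecule (1134 against 160.6 reads), called up and 0 down, 3 up adjusted over the list alone (median 0.52; camera adjusted p = 0.0399, adjusted p = 0.352 with an estimated correlation). This call was lost without Dgcr8 knockout library A (adjusted p = 0.0928), knockout library C (0.0604) or wild-type library A (0.278). Of 20 Tgf-β components 1 was called up, Gdf3, a Nodal-related ligand that rose to 4836 from 1618 reads (1.58, SE 0.25; adjusted p = 0.0364), and 0 down, 1 and 1 adjusted over the list alone (camera adjusted p = 0.55). Of 21 Smad2/3 targets 0 were called up and 1 down, Col1a1. Adjusted over the list alone, these were 1 up and 4 down (10 higher, 11 lower, camera adjusted p = 0.641). With the library-set term, 3 Smad2/3 targets were called up and 4 down, and 2 Tgf-β components up and 3 down. Lefty1 stood at 3692 against 1278 reads (log2 fold change 1.14, SE 0.64; adjusted p = 0.44, and 0.021 to 0.774 over the alternatives). Its libraries A, B and C held 7929.9, 1564.6 and 1582.1 reads in the knockout and 1813.0, 1056.9 and 964.3 in V6.5. The log2 fold change was 2.13 within A and 0.64 within B and C. With the library-set term Lefty1 was called (adjusted p = 0.021), and leaving out the A library of 1 group gave 0.36 (knockout) or 1.42 (V6.5). Lefty2 stood at 6162 against 3522 (adjusted p = 0.357; 0.0205 with the library-set term, in a range of 0.0205 to 0.67 over the alternatives), Tgfbr2 at 104.2 against 144.3 (0.933), Smad7 at 1015 against 1020 (0.874) and Skil at 7453 against 5785 (0.744). Further single calls in lists that did not pass were Zbp1, a nucleic-acid sensor (235.7 against 27.46 reads), Otx2, Zeb1, Cldn6, Dab2 and Rhox5. For the lists of Zbp1 (interferon response; median 0.01, mean -0.33) and Otx2 (primed epiblast; median -0.27, mean -0.06) camera's direction was up, at adjusted p of 0.725 and 0.977. The microRNA pathway list held 1 called up, Ago1, and 0 down, 4 and 1 adjusted over the list alone (13 tested; camera adjusted p = 0.0749).

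Both knockouts shared changes in exonic RNA. Called up in both were Lats2, Ago1, Smyd1, Msln, Fat2, Sohlh2, Gpx2, a glutathione peroxidase (1127 against 174.7 reads for Dicer, 812.9 against 60.68 for Dgcr8), and St8sia1, a ganglioside synthase (1706 against 304.2, and 1103 against 144.9). Called down in both were Lin28a, Sfmbt2, a Polycomb-group gene (485.5 against 3039, and 506.9 against 4342), Pim2 (413.3 against 3701, and 373.7 against 2110), Tro and Usp26. Among 12346 genes tested in both comparisons, 30 were called up in both, where independent lists would share 1.02 (one-sided Fisher's exact test, p = 6.05e-37), and 5 down in both against 0.146 (p = 2.93e-07). The 2 comparisons share no library, but genes are not independent replicates. Across genes the log2 fold changes correlated at Pearson's r of 0.374 and Spearman's rho of 0.372.

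The 35 genes shared in direction numbered 674 with the library-set term. Without Dicer knockout library A there were 24, without B 0 and without C 0, and without TFC library A 54, without B 5 and without C 0. Without Dgcr8 knockout library A there were 61, without B 0 and without C 0, and without V6.5 library A 39, without B 0 and without C 0.

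**Figure D2:**
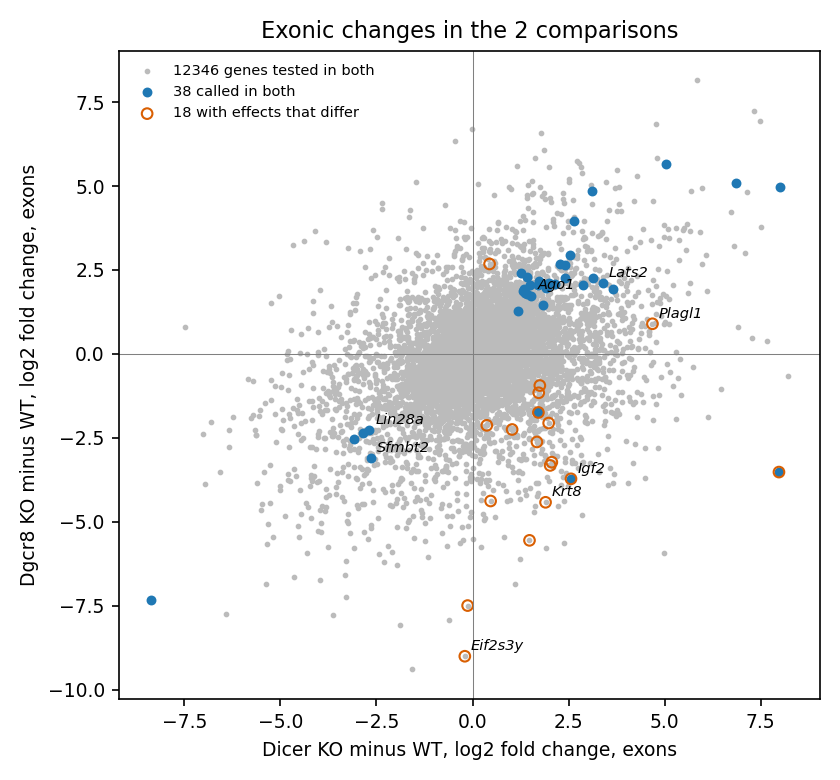
Exonic log2 fold change of each of 12346 genes in Dicer knockout minus TFC (horizontal axis) against Dgcr8 knockout minus V6.5 (vertical axis). Filled points are the 38 genes called in both comparisons and open rings the 18 genes whose effects differ by the test of the difference. Of the 38, 35 lie on the same side in both, and 3, Igf2 and Fhl1 among them, do not.

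Other genes moved apart. Fhl1, a LIM-domain protein, and Igf2 were called up in Dicer knockout and down in Dgcr8 knockout, among 3 such genes where independent lists would give 0.663 (one-sided Fisher's exact test, p = 0.0286), and 0 genes went the opposite way. This excess was absent in added fits. Fitting the library-set term gave 50 such genes where 80.5 would be shared (one-sided Fisher's exact test, p = 1), and 10 the opposite way against 56.3. With B and C alone there were 5 against 3.61 (one-sided Fisher's exact test, p = 0.293), and 3 against 1.2. By limma's test of the difference over 12 libraries, effects differed in 18 genes, 17 with the higher effect in Dicer and 1, Sfrp1, a secreted Wnt inhibitor, with the higher in Dgcr8. Differences in log2 fold change, Dicer minus Dgcr8, were 8.80 (SE 1.14) for Eif2s3y, 7.37 for Uty, 7.03 for Krt18, 6.32 for Krt8 and 6.28 (SE 0.55) for Igf2. Keratins and Tagln, a smooth-muscle actin-binding protein, were thus lower in Dgcr8 knockout by test and stood at 651.0 against 178.2 reads (Krt8), 626.9 against 217.5 (Krt18) and 429.7 against 103.8 (Tagln) in Dicer knockout and TFC. At an unadjusted p under 0.05 there were 869 genes, 339 were called with the library-set term (226 higher in Dicer and 113 in Dgcr8), and 627 with libraries B and C alone. The 18 became 11 without Dicer knockout library B or C, 44 without TFC library A, 49 without Dgcr8 knockout library A, 101 without V6.5 library A and 11 without V6.5 library B.

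Intronic reads, a readout of unspliced RNA, also changed in both knockouts. In Dicer knockout, intronic Smyd1 rose to 1488 from 15.47 reads (log2 fold change 8.10, SE 1.10; adjusted p = 0.00529), Tmprss5, a serine protease, to 852.0 from 41.95 (4.67, SE 0.61; 0.00529) and Plagl1 to 811.2 from 42.01 (0.0117), while Msln stood at 421.1 against 1.69. Pfkp, a phosphofructokinase, fell by 2.35 (SE 0.37), from 4578 to 803.3 intronic reads (adjusted p = 0.00954), and Aire (-2.20), Tango6 (-2.18) and Snd1 (-1.97) fell too. The annotated spans of Aire (chromosome 10, 78030022 to 78043610, minus strand) and Dnmt3l (78041947 to 78063622, plus strand) overlap, so the Aire value is uncertain. In Dgcr8 knockout, intronic Megf11 rose to 823.7 from 6.82 reads (7.43, SE 0.83; adjusted p = 0.00122), Tmprss5 to 740.7 from 22.65, Msln to 300.8 from 4.04 and Fcgr2b, an Fc receptor, to 222.2 from 3.52. T (511.6 intronic reads in V6.5; 11.85, 827.0 and 696.0 in its libraries A, B and C), Fgf8 (156.4) and Piezo2 (109.6) were listed at 0 in the knockout, and Car4 stood at 0.569 against 170.5. Without V6.5 library B or C, intronic T was not called (adjusted p = 0.247 and 0.236).

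In Dicer introns 32 of 11625 genes were called up and 9 down by limma. An unadjusted p under 0.05 was found for 1176 genes, and in 2007 (17.3%) the groups did not overlap. The 41 calls were 1 without a variance trend, 91 with the library-set term and 0 with libraries B and C alone (1163 at an unadjusted p under 0.05), 13 without knockout library A, 0 without B (739 at an unadjusted p under 0.05), 1 without C, 1 without wild-type library B and 2 without C. In Dgcr8 introns 119 of 10749 genes were called up and 45 down, 1558 had an unadjusted p under 0.05, and in 2121 (19.7%) the groups did not overlap. The 164 calls were 451 with the library-set term, 26 without knockout library B, 72 without C, 40 without wild-type library B and 40 without C. In Dicer introns ribosomal protein genes were lower in 26 of 30 members (0 called, 0 adjusted over the list alone; median -0.38; camera adjusted p = 4e-04, adjusted p = 0.502 with an estimated correlation).

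Intronic reads of naive pluripotency genes were higher in Dgcr8 knockout in 17 of 21 members, with Nanog called up (376.5 against 147.7 reads; 1.35, SE 0.32; adjusted p = 0.0495) and 0 down, 2 up adjusted over the list alone (median 0.76; camera adjusted p = 0.00116, 0.0756 without V6.5 library C, adjusted p = 0.482 with an estimated correlation). Mesoderm markers were lower in 4 of 4 members, 2 called (T and Fgf8) and 4 adjusted over the list alone (median -6.34; camera adjusted p = 1.56e-05, adjusted p = 0.42 with an estimated correlation). Fibroblast markers were lower in 4 of 5, with Acta2 called and 4 adjusted over the list alone (median -3.80; camera adjusted p = 0.00238, adjusted p = 0.42 with an estimated correlation). Y-linked genes were lower in 3 of 3, with Eif2s3y and Uty called and 3 adjusted over the list alone (camera adjusted p = 0.000147, adjusted p = 0.257 with an estimated correlation). Adhesion genes were lower in 10 of 14, with Cldn6 called and 1 up and 5 down adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.42 with an estimated correlation). That call was lost without V6.5 library B (0.0687) or C (0.0756). Ribosomal protein genes were lower in 25 of 30, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.482 with an estimated correlation), a call lost without Dgcr8 knockout library B (0.256), knockout library C (0.148) or V6.5 library A (0.308).

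MiR-290 targets gained exonic beyond intronic RNA in Dgcr8 knockout by camera at the preset correlation, and less firmly in Dicer knockout. In Dgcr8 knockout 11 of 12 measured members had a higher exon minus intron value (median log2 difference 1.22; camera adjusted p = 2.38e-06, adjusted p = 0.115 with an estimated correlation), 0 called over all genes and 5 up adjusted over the list alone. In Dicer knockout 7 of 11 did (median 0.59; camera adjusted p = 0.0473, adjusted p = 0.505 with an estimated correlation), 0 called and 1 up adjusted over the list alone. The Dicer call was lost with the library-set term (0.0727), and without knockout library A (0.136) or B (0.0688) or TFC library A (0.309) or C (0.339); the Dgcr8 call held without any 1 library. Fibroblast markers in Dgcr8 were higher in 5 of 5 (median 0.85; camera adjusted p = 0.00759, adjusted p = 0.457 with an estimated correlation), 0 called and 1 up adjusted over the list alone, a call lost without Dgcr8 knockout library A (0.124) or V6.5 library C (0.0806).

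No single gene passed in exon minus intron: limma called 0 of 11010 in Dicer, with 435 at an unadjusted p under 0.05, and 0 of 10371 in Dgcr8, with 548. Counts with the library-set term were 0 and 0. Taking exonic and intronic libraries as independent gave 1 in Dicer and 0 in Dgcr8. In simulations, limma called 0% of 4-fold changes in either without the library-set term, and 99% in Dicer and 100% in Dgcr8 with it. Of 2-fold changes, it called 0% without the term, and 21% in Dicer and 54.7% in Dgcr8 with it. The deviation of library A was built into the simulated reads, and all their genes and libraries shared 1 dispersion, the median from knockout B and C. In the real introns, B and C correlated at r of 0.565 in TFC and 0.766 in Dicer knockout. The simulated shares may thus be too high for the real libraries, and the count of 0 does not exclude such changes.

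Messages with a 3' UTR match to the miR-290 seed, AAGUGCU, were higher in exons of both knockouts. The test of exonic against intronic change passed in Dgcr8 at the preset correlation alone and did not pass in Dicer. In Dicer exons the median log2 fold change was 0.16 over 2676 genes with a site and -0.05 over the other 10215 (camera adjusted p = 0.0354, adjusted p = 0.0476 with an estimated correlation). In Dgcr8 exons it was 0.08 over 2630 genes and -0.12 over 9831 (camera adjusted p = 0.0383, adjusted p = 0.818 with an estimated correlation). Among genes with a site, 51 were called up and 3 down in Dicer, and among the others 78 up and 27 down. In Dgcr8 these were 35 up and 11 down with a site, and 54 up and 54 down without. In Dicer introns the medians with and without a site were 0.05 and 0.05 (adjusted p = 0.945), and in Dgcr8 introns -0.04 and -0.06 (adjusted p = 0.983). Exon minus intron medians were 0.11 and -0.10 in Dicer (adjusted p = 0.179, and 0.467 with an estimated correlation) and 0.16 and -0.04 in Dgcr8 (adjusted p = 0.0307, and 0.676 with an estimated correlation).

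In a permutation test with 10000 matched random lists, the AAGUGCU median lay at percentile 100 in exons and in exon minus intron of both knockouts (two-sided permutation p = 2e-04, the smallest these lists can give), and at percentile 32.62 in Dicer introns and 93 in Dgcr8 introns. The related miR-17 family seed, AAAGUGC, also lay at percentile 100 in these 4, and passed camera in Dgcr8 exon minus intron (adjusted p = 0.0307, and 0.676 with an estimated correlation). That call was lost without Dgcr8 knockout library B (0.324) or C (0.225) or V6.5 library A (0.936). AAAGUGC did not pass in Dicer exons at the preset correlation (0.0702, but 0.0476 with an estimated correlation) or in Dgcr8 exons (0.0507, and 0.818). The other 4 stem-cell seeds did not pass camera at the preset correlation in any comparison. In Dicer exons, miR-19 and miR-130 lay at percentile 100 (adjusted p = 0.124 and 0.111, and 0.0476 for both with an estimated correlation), miR-25 at 99.18 and miR-15 at 99.83. In Dgcr8 exons these 4 lay at 99.24, 100, 99.92 and 5.38. In exon minus intron they lay at 98.53, 99.26, 93.77 and 72.12 in Dicer, and at 99.99, 99.92, 82.18 and 16.59 in Dgcr8. Of the comparison seeds in Dicer exons, let-7, miR-122 and miR-1 lay at percentiles 17.56, 29.2 and 91.13, and miR-124 at 100. In Dgcr8 exons they lay at 13.32, 44.49, 37.01 and 22.85. In exon minus intron these comparison seeds lay at 63.99, 30.34, 68.03 and 99.84 in Dicer, and at 44.38, 12.56, 67.24 and 98.93 in Dgcr8. The miR-124 comparison seed thus lay above most random lists in exon minus intron of both knockouts. Random lists describe these libraries and carry no spread between them. For AAGUGCU in Dicer exons the camera call was lost without knockout library B (0.162) or C (0.0997) or TFC library A (0.395) or C (0.0518). In Dgcr8 exons it was lost without knockout library B (0.312) or C (0.557) or V6.5 library A (0.999), and in Dgcr8 exon minus intron without the same 3 libraries (0.324, 0.225 and 0.936).

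**Figure D3:**
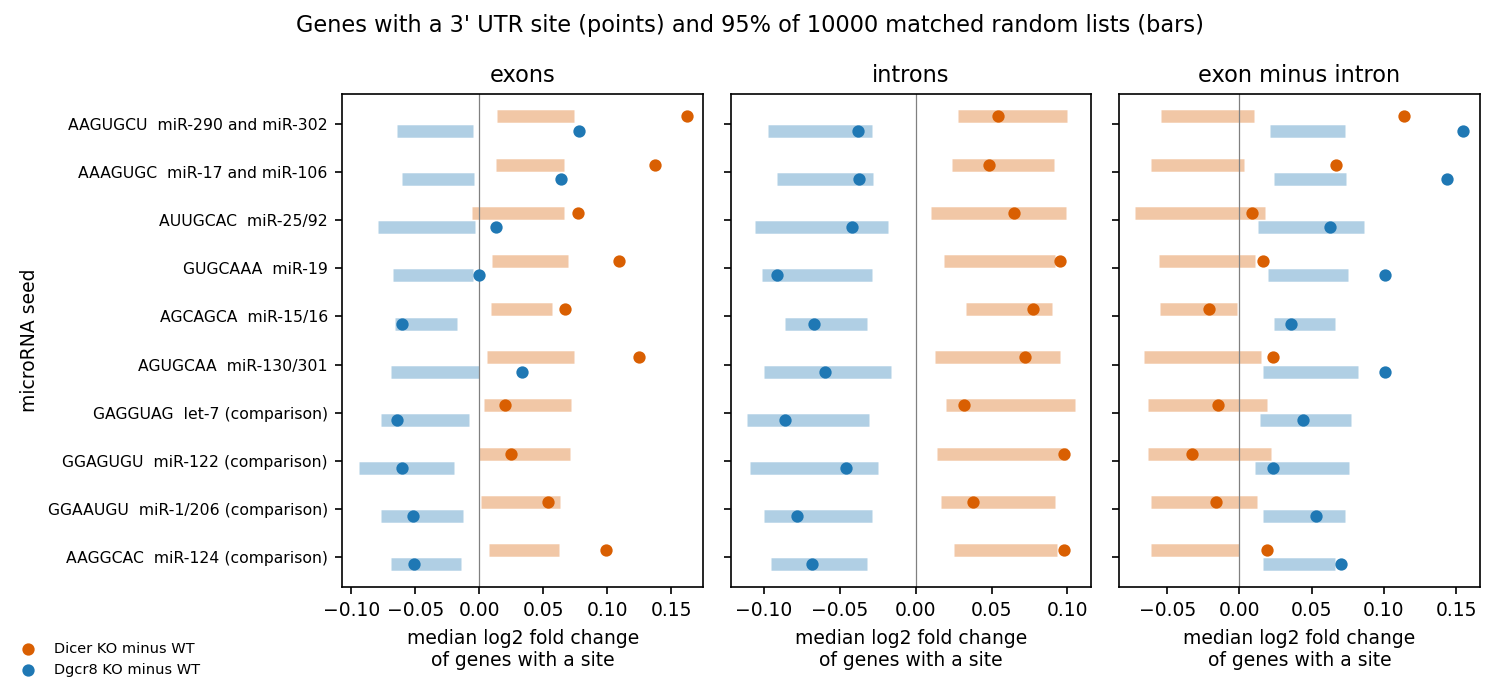
Median log2 fold change (horizontal axis) of genes with a 3' UTR match to each of 10 microRNA seeds (vertical axis), for exons, introns and exon minus intron, Dicer knockout minus TFC and Dgcr8 knockout minus V6.5. Points are medians and bars hold 95% of 10000 random lists matched on level and 3' UTR length. AAGUGCU lies above its bars in exons (0.16 and 0.08) and exon minus intron (0.11 and 0.16) of both knockouts.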

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

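Chosen only after the result was seen were the read-depth test, both tests of a change shared by the knockouts, the counts of other splits and the values with a library-set term. Exonic effects differed between Dicer and Dgcr8 by limma's test of the difference in 18 genes, and these call for a closer look because the same contrast, knockout minus wild type, gave different effects. Differences in log2 fold change, Dicer minus Dgcr8, were 8.80 for Eif2s3y, 7.37 for Uty, 7.03 for Krt18, 6.32 for Krt8, 6.28 for Igf2, 5.29 for Tagln, 4.85 for Rhox5, 3.78 for Plagl1, 3.46 for Fhl1 and 2.88 for Ctgf. Genotype and cell line differ together within and between the comparisons, so a difference may come from any line's own state. For Eif2s3y and Uty, whether the Dgcr8 knockout line carries a Y chromosome was not tested.

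The markers called lower in Dgcr8 knockout than in V6.5 were T, Wnt3, Krt8, Krt18, Col1a1, Acta2 and Tagln. For Krt8, Krt18 and Tagln, effects differed by limma's test of the difference, which argues against an equal fall in both knockouts. Their lowest difference, 5.29, adds no support, as they were picked by this test and by their call in Dgcr8. None of them was called in Dicer exons (limma adjusted p = 0.107, 0.332 and 0.154). For T, Wnt3, Col1a1 and Acta2 the median log2 fold change in Dicer exons was -0.68 at levels of 3.0 to 59.5 reads, with adjusted p of the difference from 0.387 to 0.954, so a shared change cannot be told apart from none. Fibroblast feeder cells in the V6.5 libraries stay open. The group mean of Col1a2 reached 61.3% of the Col1a1 level there (842.5 against 1374.5 reads). Libraries A, B and C of V6.5 held 170.1, 905.4 and 1452.0 reads of Col1a2, and 1000.4, 1770.0 and 1353.2 of Col1a1. Col3a1 stood at 113.9, Thy1 at 63.0, Postn at 34.4 and Col6a1 at 22.9, and Krt8, Krt18 and T are no fibroblast genes. Of the fibroblast list 12 members were lower in Dgcr8 knockout and 3 higher, among these Vim (7677.3 against 2722.7 reads). Per the labels' protocols, cells grew on gelatin. The loss of Dgcr8 itself and a difference between the lines stay open as untested. The V6.5 libraries also differed among themselves in T, Wnt3, Sox2 and Nanog, as given above, and the cause was not tested.

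Library A deviated from B and C in a like way in all 4 groups, with a median r of 0.77 between the groups' exonic deviations (0.7 to 0.81) and 0.3 in introns. Read depth is argued against, since A was the deepest library in 3 groups and the shallowest in V6.5, where its deviation still correlated with the others at 0.7 or more. Exon length is argued against as well (Spearman's rho -0.26 to 0.03; median r 0.78 after taking out its trend). Transcript GC content may account for part: rho was 0.65 to 0.84 in the 4 groups, and taking out medians of 20 GC bins lowered the median r from 0.77 to 0.54, so other causes remain. No biological explanation was tested, and the labels give no batch.

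For counts within a comparison, 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other gave 162 and 0 genes in Dicer exons, 41 and 0 in Dicer introns, 161 and 0 in Dgcr8 exons, and 164 and 0 in Dgcr8 introns, so that 1 of 10 splits reached the real count in each. In exon minus intron they gave 0 and 4 genes in Dicer and 0 and 1 in Dgcr8, and 10 of 10 splits reached 0. With the library-set term, other splits reached 269 genes in Dicer exons (real 1620), 767 in Dicer introns (real 91) and 1008 in Dicer exon minus intron (real 0). These splits put both A libraries in the same arm, so with the term fitted they set 1 TFC library against 3 others. In TFC introns, library B correlated with A at r of 0.511 and with C at 0.565, and A with C at 0.729. In Dicer knockout introns these r were 0.773 (A with B), 0.766 (B with C) and 0.794 (A with C). In Dicer introns the library-set term thus does not take up the distance of TFC library B. For genes called in both comparisons in the same direction, 1 of 100 splits gave 35 or more and the highest other gave 0. No other split of either comparison had a call, so this share follows from the 10 splits of each and does not exclude chance. For effects that differ, 2 of 100 splits gave 18 or more, 11 had any call, and the highest other gave 190. That split kept the Dicer groups and put Dgcr8 knockout A with V6.5 A and B. Splits that keep the groups of 1 comparison still hold its effect, so this share does not exclude chance, and a structure of the libraries was not separated from the Dicer effect that the split kept.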

How the results depend on the processing

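Library-set, B and C alone, limma-voom and independent-library fits, estimated correlations for seeds, and lists and seeds without each library, were chosen after seeing the data; for each change below the cause was not tested. Genes called in Dicer exons (162) were 35 without a variance trend, 21 with limma-voom, 1270 with limma-voom and the set term, 1620 with the set term, 63 with B and C alone, and 0 to 480 without 1 library. Dicer introns (41) gave 82 with pseudocount 8, 1 without a trend, 64, 124, 91, 0 and 0 to 37 in that order; Dgcr8 exons (161) gave 50, 2145, 2160, 2028 and 0 to 466 from limma-voom on. Dgcr8 introns (164) gave 304 with pseudocount 8, 107 without a trend, 333 with limma-voom and the set term, 451 with the set term and 26 to 176 without 1 library. Exon minus intron (0 and 0) gave 1 in Dicer with libraries taken as independent. Genes shared in direction (35) were 674 with the set term and 0 to 61 without 1 library; effects that differ (18) were 339 with the set term, 627 with B and C alone and 11 to 101 without 1 library.

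Gene lists past the test numbered 0 with an estimated correlation in all 6 comparisons. Dicer introns (1) gave 2 with pseudocount 8, a mean of at least 50 or the set term, and 1 to 2 without 1 library. Dicer exon minus intron (1) gave 2 with pseudocount 8, 0 with the set term or B and C alone, and 0 to 3 without 1 library; Dgcr8 exon minus intron (2) gave 1 with B and C alone and 1 to 4 without 1 library. Seeds in Dicer exons (1) were 4 with an estimated correlation, 3 with 8mer sites, 2 with a mean of at least 50, 0 with B and C alone and 0 to 5 without 1 library; Dicer exon minus intron (0) gave 1 with 8mer sites and 0 to 2 without 1 library. Dgcr8 exons (1) gave 3 with 8mer sites, 0 with an estimated correlation or 6-mer matches, 2 with a mean of at least 50, the set term or B and C alone, and 0 to 5 without 1 library; Dgcr8 exon minus intron (2) gave 0 with an estimated correlation, 6-mer matches or B and C alone and 0 to 4 without 1 library.

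Log2 fold changes that turned were of uncalled genes: Skil in Dicer exons -0.06 and Cdkn1a in Dgcr8 exons -0.28 with B and C alone; without 1 library, ranges were -0.007 to 0.58 for Dgcr8, -0.16 to 0.39 for Pou5f1 and -0.24 to 0.03 for Sox2 in Dicer exons, and -0.16 to 0.46 for Cdkn1a, -0.21 to 1.02 for Smad7 and -1.05 to 0.16 for Tgfbr2 in Dgcr8 exons. Values of named genes kept direction and side of the threshold in 790 cases and lost their call in 106 under other planned choices, and 327 and 432 without 1 library. An arm left with 2 libraries is assumed to vary like the other. The planned count-model tests were not run. The deposited values are normalised means, and the reads recovered from them were fitted only with limma-voom. No paired analysis was possible because the deposited columns are group means and the recovered libraries carry no replicate number; the library-set term matches libraries across groups by likeness in the data, not by a label.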

Other observations

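The values of Y-linked genes other than Eif2s3y and Uty were chosen after they were seen. Of 4 Y-linked genes, all stood lower in Dgcr8 knockout than in V6.5, in exons and introns. Intronic Eif2s3y stood at 11.1 reads in Dgcr8 knockout and 234.7 in V6.5, and intronic Uty at 4.6 and 218.7. Intronic Ddx3y stood at 18.0 and 83.5, and intronic Kdm5d at 0.0 and 10.8. Whether the Dgcr8 knockout line carries a Y chromosome was not tested, so these values cannot be read as regulation of the genes. Exonic Eif2s3y, a translation factor subunit, stood at 3.1 reads in Dgcr8 knockout and 1213.5 in V6.5, and at 1787.4 and 2080.7 in Dicer knockout and TFC. Uty, a histone demethylase homologue, stood at 3.1 and 401.2, and at 992.8 and 1099.1. Kdm5d stood at 2.1 and 15.6, and at 17.3 and 261.7. Ddx3y stood at 218.4 and 1376.3, and at 4843.9 and 3373.3, and its reads may be shared with its X-linked copy Ddx3x, which was not tested; without any 1 Dgcr8 library the 3 tested Y-linked genes passed camera in exons at adjusted p of 1.66e-06 to 0.00119, but with all libraries and an estimated correlation the adjusted p was 0.296.

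Genes with a 3' UTR site of AAGGCAC, the seed of the neuronal miR-124 set in advance for comparison, also lay above matched random lists in Dicer exons, at percentile 100, though camera's adjusted p was 0.124. Sites of the stem-cell families AAGUGCU and AAAGUGC occur in 48.1% of the 3093 genes with such a site and in 27.3% of the others. Their presence is argued against as the whole cause: among 8730 genes without these sites, the 1605 with an AAGGCAC site had a median log2 fold change of 0.04, against a range of -0.08 to -0.01 in random lists (percentile 100). Transcript GC content is argued against in the same way, since with GC content matched the median was 0.10 against 0.01 to 0.07 (percentile 100). The seed also lay at percentile 98.68 in Dicer introns. In exon minus intron it lay at 99.84 in Dicer and 98.93 in Dgcr8 (camera adjusted p = 0.374 and 0.431). In Dgcr8 exons and introns it lay at 22.85 and 35.47. No biological explanation was tested, so a percentile of 100 may arise without the matching microRNA.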
